A study of Mus musculus with 10 samples.

How the data were processed

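Total RNA of 5 cell populations purified by fluorescence-activated cell sorting from the paw pads of wild-type female CD1 mice was measured on 10 mouse expression arrays, 2 per population. Per the labels' protocols, RNA was extracted with Trizol and biotin-labelled cRNA was made from total RNA with the standard Affymetrix procedure. The markers used for sorting and the number of animals behind each array are not given in the labels, which call the arrays of a population biological replicates 1 and 2. Per the submitters' processing notes, the deposited values are signal intensity from MAS5, whose version is not given. They are on a linear scale, from 0.1 to 72213, and the trimmed mean without the highest and lowest 2% was 500 on every array. No detection calls were used here.

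Of 22690 probe sets, 64 controls were left out of all tests. The gene table gave 1 symbol for 20380 probe sets and several for 691, and 1606 were not listed in it. Entrez identifiers of 20364 single-gene probe sets were found in a RefSeq table, which was used for names only and changed 0 symbols. Each of the 12393 genes was represented by its probe set with the highest mean. Among the results for named genes, 175 were of genes with several probe sets, and in 10 of these another probe set had the opposite sign, with 0 past the threshold. Signals were converted to log2 after adding 12, the 20th percentile of all values, with no further normalization. A gene was tested if it lay above the 40th percentile of the array on at least 2 of 10 arrays, which left 9304 genes.

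Genes were tested with limma 3.58.1 in R 4.3.3, in 1 linear model of all 10 arrays with moderated variances that follow the mean signal, and p-values were adjusted by the method of Benjamini and Hochberg with a threshold of 0.05. The comparisons were myoepithelial against luminal, duct basal against duct suprabasal, myoepithelial against duct basal, luminal against duct suprabasal and duct basal against epidermis, the difference between the layer differences of gland and duct, an F test over the 5 populations, and all pairs of populations. Comparisons that share a population share its arrays. P-values measure the spread between these arrays, which the model takes as equal in all 5 populations. The arrays share replicate numbers, but the labels describe no pairing and the numbers were not used as a factor. Log2 differences are given with their standard error (SE). A gene belonged to the set of a population if it was higher there than in each of the 4 others, past the threshold and by at least 2-fold.

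The design, the alternatives and 25 gene lists were fixed before the data were examined. There were 14 program lists (contractile, basal keratinocyte, simple epithelial, secretory coil, ductal ion absorption, epidermal differentiation, wound and stress keratin, cell cycle, Wnt and Eda, Bmp, Tgfb and Id, Notch, hair follicle stem cell, basement membrane and matrix, and mucin, lipocalin and host defence genes). The 11 others were markers of fibroblasts, endothelium, immune cells, pericytes, melanocytes, Schwann cells, Merkel cells, red blood cells, skeletal muscle and adipocytes, and early response genes of tissue dissociation. Some genes stand in more than 1 list. Lists with at least 3 tested members were tested against all other genes with camera of limma, with a preset correlation of 0.01 between genes and again with the correlation estimated from the arrays, adjusted over the 126 tests of 21 lists in 6 comparisons. Of these tests 64 passed with the preset correlation and 0 with the estimated correlation. The smallest adjusted p of camera with the estimated correlation was 0.108. The fit has 5 residual degrees of freedom, and the power of the tests with an estimated correlation was not examined.

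Genes are named by a rule: adjusted p under 0.05, at least 2-fold, both arrays of the higher population above both of the lower, and a mean in the higher population above the median of all genes tested. The 8 largest per direction and up to 4 members of each list and direction qualified, with 5 genes per population set, and other list members are named to describe their list. The spread between arrays of a population, which has 2 each, limits the precision. Simulated arrays had the same mean in all populations apart from changes added to duct basal cells, and 1 spread per gene shared by all. The fit recovered 22% of 2-fold, 82% of 4-fold, 92% of 8-fold and 100% of 16-fold changes between the duct layers. There were 50 genes at each size, and 9 of the 157 calls were false. The real duct suprabasal arrays spread more than those of the other populations, so recovery there may be lower. Far fewer genes were changed than the 1505 that passed between the real duct layers. That made the adjusted threshold stricter in the simulation, so these rates need not hold for the real arrays.

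The alternatives were pseudocounts of 1 and 47, quantile normalization, no filter or a filter at the 60th percentile, variances without a trend, all 16049 probe sets, leaving out probe sets that may match several transcripts, leaving out each array in turn, a block for the replicate number, a fit of only the arrays compared, and fry, which tests a list against no change rather than against all other genes, in place of camera. The list tests were repeated only with fry, quantile normalization, the block and arrays left out. Where an array is left out, the lone array of its population is assumed to vary like those of the other populations. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.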

Results

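Transcript levels were measured in 5 cell populations of mouse paw pads, the main site of sweat glands in mice. A sweat gland has a secretory coil, in which contractile myoepithelial cells surround secretory luminal cells, and a straight duct of basal and suprabasal cells that opens into the thick epidermis of the sole. The populations were duct basal, duct suprabasal, gland myoepithelial and gland luminal cells and palmoplantar epidermis, all purified by fluorescence-activated cell sorting from wild-type female CD1 mice. Each was measured on 2 arrays labelled as biological replicates. The labels do not say how many animals stood behind an array, and the small number of arrays limits the precision of every estimate. The median signal of a probe set was 65.7 and 67.3 on the epidermis arrays and between 92.7 and 120.1 on the 8 others. Across the 9304 genes tested, which are not independent replicates, the correlation between the arrays of a population was 0.908 in duct suprabasal cells and 0.963, 0.963, 0.974 and 0.981 in duct basal, myoepithelial, luminal and epidermal cells. In duct suprabasal cells 1864 genes differed more than 2-fold between the arrays, against 817 in duct basal, 732 in myoepithelial, 611 in luminal and 501 in epidermal cells.

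Levels of keratin, water channel and contractile transcripts varied among the 5 populations. Krt14, a keratin of stratified basal epithelium, reached a signal of 34865 ± 1594 (SD, n = 2) in duct basal cells and 9145 ± 352 in myoepithelial cells. Krt10, a keratin of differentiating epidermis, was brightest in epidermis, at 41057 ± 1135, and Aqp5, the water channel of secretory cells, was brightest in luminal cells, at 20529 ± 5315. Myh11, the smooth muscle myosin heavy chain, reached 18928 ± 207 in myoepithelial cells and no more than 90.7 ± 58.0 elsewhere. In the limma F test over the 5 populations, 6089 of the 9304 genes differed at an adjusted p under 0.05 (65.4%).

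**Figure D1:**
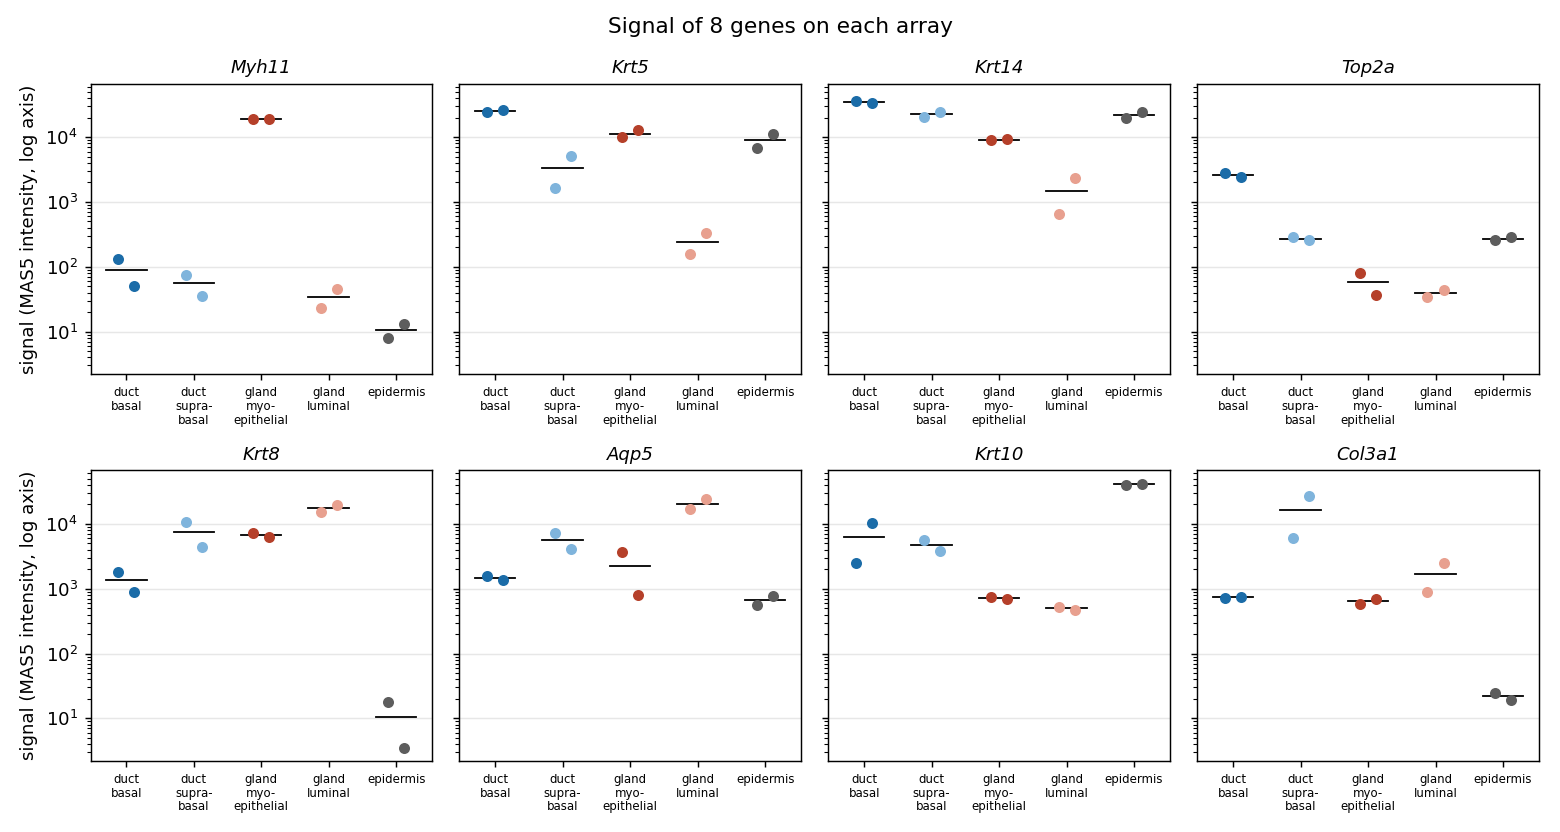
Signal of 8 genes on each of the 10 arrays (MAS5 intensity, log axis), with the arrays of each population as points and their mean as a bar. Myh11 stood at 18928 in myoepithelial cells against 90.7 or less in the other populations, and the Col3a1 signals of the duct suprabasal arrays lay far apart.

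The myoepithelial and luminal layers of the gland coil were compared to find what sets its outer and inner cells apart. Myoepithelial cells held the transcripts of smooth muscle contraction and of anchorage to the basement membrane. They also held more transcript of Wnt and Eda pathway genes, a Wnt inhibitor among them, which does not show that the pathway is active. Luminal cells held transcripts of simple epithelia, secretion and ion transport. All 13 contractile genes tested were higher in myoepithelial cells, led by Myh11 (log2 difference 8.71, SE 0.46, adjusted p = 7.65e-06) and Cnn1, which encodes calponin (7.23, SE 0.35, adjusted p = 5.72e-06). Of 15 basal keratinocyte genes 13 were higher, among them Lama3, a chain of laminin-332 (7.52), Col17a1, a hemidesmosomal collagen (7.37), and Trp63, the transcription factor of stratified epithelia (6.20, SE 0.22), and only the integrin subunit Itgb4 was lower (-1.30, SE 0.24). All 15 simple epithelial genes tested had a lower mean in myoepithelial cells and 14 passed, with Cldn7, a tight junction claudin (-4.29), and the keratin Krt19 (-4.02) among them. Krt8 (-1.37) was the member that did not pass.

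Secretory coil genes were lower in myoepithelial cells for 12 of 16 members, with the chloride and bicarbonate channel gene Best2 at -4.79 (SE 0.92, adjusted p = 0.00477) and Foxi1, a transcription factor of ion-transporting cells, at -4.03 (SE 0.86, adjusted p = 0.00740). Of 10 ductal ion absorption genes 9 were lower, including the proton pump subunit Atp6v1b1 (-4.19) and Scnn1g, a subunit of the epithelial sodium channel (-2.68). Of 15 Wnt and Eda pathway genes 10 were higher in myoepithelial cells and none lower, with Sfrp1, a secreted Wnt inhibitor, at 6.97 (SE 0.46) and Lgr5, the R-spondin receptor that marks several epithelial stem cells, at 4.89 (SE 0.33, adjusted p = 2.63e-05). Basement membrane and matrix genes were higher for 9 of 15 members, led by the collagen IV gene Col4a1 (5.39), and lower for 1. In the Notch pathway 4 genes were higher and 4 lower of 14. The ligand genes Dll1 (3.75) and Jag1 (3.54) were on the myoepithelial side and the receptor gene Notch3 (-2.45) on the luminal side. For Jag1, 1 of 2 probe sets had the opposite sign and did not pass. Hair follicle stem cell genes were higher for 6 members of 11, including Tbx1 (3.65) and Krt15 (2.88), and lower for 2.

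Across all genes 2890 of 9304 passed in the limma fit, 1539 higher and 1351 lower in myoepithelial cells, and 2147 of them differed at least 2-fold. Between the arrays numbered 1 and between those numbered 2, the direction was the same for 2890 of the 2890. With 2 arrays per population a gene that passes can hardly do otherwise. This count, here and in the comparisons below, is therefore no test of reproducibility. Adjusted over the list alone, 13 contractile, 14 basal keratinocyte, 15 simple epithelial, 12 secretory coil, 9 ductal ion absorption, 11 Wnt and Eda, 11 basement membrane, 9 Notch and 8 hair follicle stem cell genes passed. The contractile list shifted as a set against all other genes (camera, adjusted p = 3.25e-13), with an adjusted p = 0.108 with an estimated correlation. For the basal keratinocyte list the adjusted p was 2.08e-08 (adjusted p = 0.108 with an estimated correlation), for the Wnt and Eda list 9.35e-06 (adjusted p = 0.108 with an estimated correlation), and for the simple epithelial list 5.96e-08 (adjusted p = 0.330 with an estimated correlation). The secretory coil list gave an adjusted p of 3.24e-05 (adjusted p = 0.333 with an estimated correlation), the ductal ion absorption list 3.24e-05 (adjusted p = 0.331 with an estimated correlation), and the basement membrane list 0.00206 (adjusted p = 0.490 with an estimated correlation). The Notch list did not shift as a set (adjusted p = 0.769), nor did the cell cycle list, with 3 members higher and 2 lower of 21 (adjusted p = 0.397). The hair follicle stem cell list gave an adjusted p of 0.0419 (adjusted p = 0.342 with an estimated correlation), and this call ended without myoepithelial array 1 (0.0706), duct suprabasal array 1 (0.0689), duct basal array 2 (0.0503) or duct suprabasal array 2 (0.0800) and, as an alternative added after the data were seen, without myoepithelial array 1 and duct suprabasal array 2 together (0.119). The count of genes was 1634 without luminal array 1, 1577 without luminal array 2 and 1422 without myoepithelial array 2.

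Beside the luminal and myoepithelial gene groups stood transcripts that mark other cells. Whether the immune, fibroblast and pericyte transcripts came from such cells was not tested. Krt18 had a signal of 3744 on myoepithelial array 1 and 444 on array 2, and genes at least 10-fold brighter in luminal cells than on myoepithelial array 2 (164 genes) lay above it on array 1 by a median of 16.5% of their luminal level. The median signal of the simple epithelial list was 578 on myoepithelial array 1 and 149 on array 2, and that of the secretory coil list 686 and 213. The log2 differences of Best2 and Foxi1 were -6.56 and -5.42 without array 1, and -3.03 and -2.64 without array 2. All 7 immune cell genes tested were higher in myoepithelial than in luminal cells, with the lysozyme gene Lyz2 at 3247 ± 908 and 266 ± 227 (SD, n = 2) and Tyrobp, an adaptor of myeloid receptors, at 534 ± 165 and 43.3 ± 36.0. All 7 passed when adjusted over the list alone, and the list shifted as a set (camera, adjusted p = 0.000657, and adjusted p = 0.353 with an estimated correlation). Beside the matrix genes, 2 of 8 fibroblast genes were higher in myoepithelial cells, Postn (6.57, SE 0.54) and Dcn (3.77, SE 0.76), and 1 was lower. Of 4 pericyte genes 2 were higher, including Cspg4 (2.26, SE 0.47), and 1 was lower. When adjusted over the list alone 3 fibroblast and 3 pericyte genes passed, and neither list shifted as a set (adjusted p = 0.746 and 0.620).

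The basal and suprabasal layers of the duct were compared in the same way. Duct basal cells held the transcripts of dividing cells and of basal keratinocytes. Duct suprabasal cells held more transcript of simple epithelial and secretory genes, unequally on their arrays, together with marker transcripts of fibroblasts and blood vessels. Of 21 cell cycle genes 20 were higher in duct basal cells, among them Birc5, which encodes survivin (3.78, SE 0.34, adjusted p = 0.000486), the mitotic kinase gene Cdk1 (3.49, SE 0.25, adjusted p = 0.000374) and Cdc20 (3.57), and only Ccnd1 did not pass (-0.25). Of 15 basal keratinocyte genes 10 were higher, including Dst, a linker of keratin to the hemidesmosome (4.03, SE 0.33, adjusted p = 0.000382), and Trp63 (2.73, SE 0.22), and none was lower. Of the probe sets, 2 of 4 for Dst and 1 of 3 for Trp63 had the opposite sign and did not pass. Of 15 Wnt and Eda pathway genes 5 were higher, with Wnt10a at 2.40 (SE 0.43). Lgr5 stood at 2.54 (SE 0.33) but did not meet the naming rule here.

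On the suprabasal side, 6 of 15 simple epithelial genes, 5 of 16 secretory coil genes and 2 of 10 ductal ion absorption genes passed as lower in basal cells and none passed as higher. The sodium channel subunit genes Scnn1g (-2.78, SE 0.39, adjusted p = 0.00316) and Scnn1b (-2.49, SE 0.31, adjusted p = 0.00188) were the ductal absorption genes that passed, and Orai1, a calcium entry channel gene, passed among the secretory coil genes (-1.35, SE 0.23). The median signal of the simple epithelial list was 2038 on duct suprabasal array 1 and 781 on array 2, and that of the secretory coil list 2350.2 and 718, against no more than 337 and 388 on the duct basal arrays. Of the 123 genes of the luminal set, 11 were brighter on duct suprabasal array 2 than on array 1, with a median log2 ratio of -0.57. Where the brighter luminal transcripts on array 1 came from was not tested. The lowest values among all genes in duct basal cells included Esm1, an endothelial secreted proteoglycan gene (-5.02, SE 0.52, adjusted p = 0.000900), and Lum, a fibroblast proteoglycan gene (-5.00, SE 0.82, adjusted p = 0.00559). All 8 endothelial genes had a lower mean in duct basal cells and 7 passed. Of 8 fibroblast genes 4 passed, with Col3a1 at -4.09 (SE 0.63). Col3a1 had a signal of 5966 on duct suprabasal array 1 and 26876 on array 2, against 733 ± 29.1 (SD, n = 2) in duct basal cells. In both lists 8 of 8 genes were brighter on duct suprabasal array 2 than on array 1, by a median log2 ratio of 2.35 for fibroblast and 2.36 for endothelial genes, while the median over all genes was -0.02.

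In this comparison 1505 genes passed, 738 higher and 767 lower in duct basal cells, with 1141 at least 2-fold apart and 1505 of the 1505 in the same direction within both replicate numbers. Adjusted over the list alone, 20 cell cycle, 12 basal keratinocyte, 7 Wnt and Eda, 10 simple epithelial, 10 secretory coil, 5 ductal ion absorption, 8 endothelial and 6 fibroblast genes passed. As sets, the cell cycle list (camera, adjusted p = 5.12e-18, and adjusted p = 0.108 with an estimated correlation) and the basal keratinocyte list (adjusted p = 2.08e-08, and adjusted p = 0.108 with an estimated correlation) shifted towards duct basal cells, as did the Wnt and Eda list (adjusted p = 0.000315, and adjusted p = 0.179 with an estimated correlation). The simple epithelial list (adjusted p = 2.49e-05, and adjusted p = 0.370 with an estimated correlation), the secretory coil list (adjusted p = 1.13e-05, and adjusted p = 0.330 with an estimated correlation) and the endothelial list (adjusted p = 2.55e-05, and adjusted p = 0.345 with an estimated correlation) shifted the other way. The ductal ion absorption list gave 0.0109 (adjusted p = 0.494 with an estimated correlation) and missed the threshold without duct suprabasal array 1 (0.110). The fibroblast list gave 0.0198 (adjusted p = 0.566 with an estimated correlation) and missed it without duct suprabasal array 2 (0.255), without that array and myoepithelial array 1 together (0.278), and with fry (0.158), which tests a list against no change rather than against other genes. The count of genes was 808 without duct basal array 1, 430 without duct basal array 2 and 223 in a fit of only the 4 arrays compared. With quantile normalization the median log2 difference of all genes moved from -0.02 to 0.09.

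**Figure D2:**
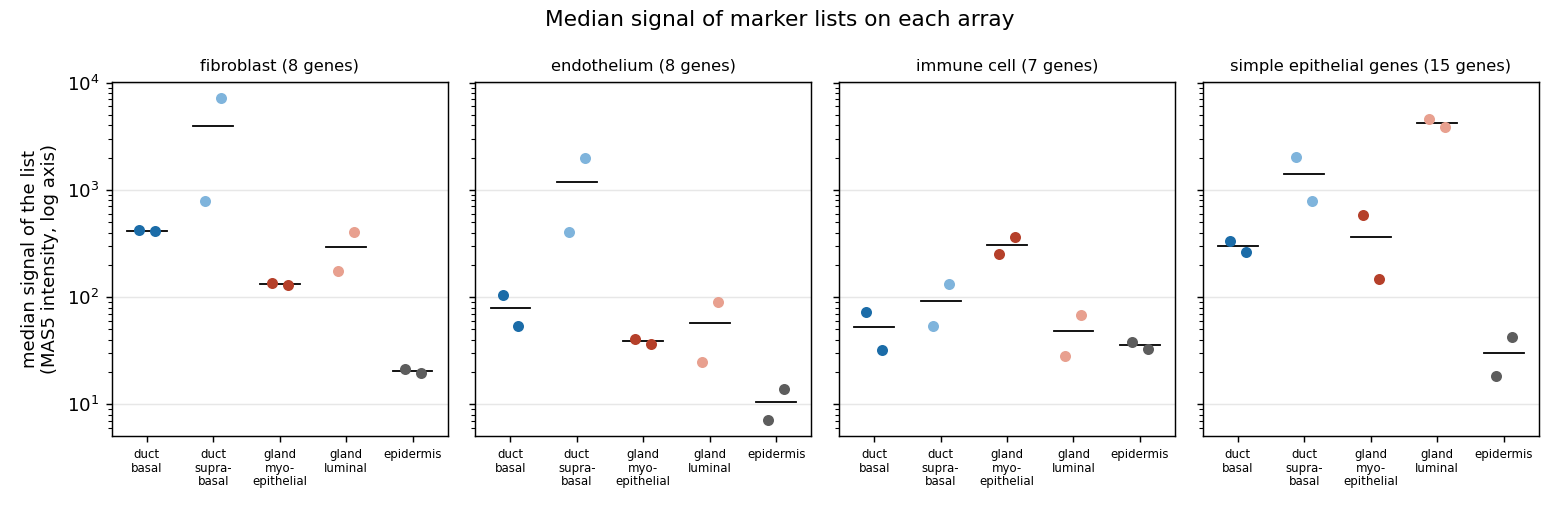
Median signal of 4 marker lists on each array (MAS5 intensity, log axis), with arrays as points and the mean of each population as a bar. Fibroblast and endothelial genes were brightest on duct suprabasal array 2, and immune cell genes on the myoepithelial arrays.

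Myoepithelial and duct basal cells, the outer layers of gland and duct, were compared to separate the coil from the duct. Myoepithelial cells held the contractile transcripts and those of collagen IV, and duct basal cells those of cell division and epidermal differentiation. All 13 contractile genes were higher in myoepithelial cells, with Cnn1 at 8.06 (SE 0.35, adjusted p = 3.82e-06) and Myh11 at 7.65 (SE 0.46). Among all genes, Pcp4, a calmodulin-binding peptide gene, was highest at 8.31 (SE 0.52), and the neural crest and glandular transcription factor gene Sox10 stood at 4.81 (SE 0.51). For Sox10, 1 of 3 probe sets had the opposite sign and did not pass. Of 21 cell cycle genes 20 were lower in myoepithelial cells, among them Birc5 (-6.08, SE 0.34, adjusted p = 1.02e-05) and Top2a (-5.31, SE 0.31). Top2a, the topoisomerase of dividing cells, had a signal of 2631 ± 247 (SD, n = 2) in duct basal and 57.8 ± 30.4 in myoepithelial cells.

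Epidermal differentiation genes were lower in myoepithelial cells for 9 of 19 members, including Krtdap, a secreted keratinocyte differentiation protein gene (-7.25, SE 0.66, adjusted p = 9.61e-05), and Krt1 (-3.84). Wound and stress keratin genes were lower for 5 of 9, with Krt16 at -4.44 and Krt6a at -4.32. Basal keratinocyte genes went both ways, 4 higher and 3 lower of 15, with Lama3 (2.49) and Itgb1 (1.77) higher and Itgb4 (-2.34) lower. In the Notch pathway 4 of 14 genes were lower, Notch1 (-3.15, SE 0.27), Nrarp, a Notch target (-4.82, SE 0.32), Hes1 (-3.09) and Jag1 (-1.68), and none was higher. Col4a1 (5.42) and Col4a2 (5.34) were among 4 higher basement membrane genes of 15, and Tnc was lower (-2.52). Of 12 mucin, lipocalin and host defence genes 7 were higher, including Lcn2 (4.09), Lyz1 (4.36) and Clu (3.22), and 2 were lower. In the same comparison 5 of 7 immune cell genes were higher, with Tyrobp at 3.86 (SE 0.65). Lyz2 (4.28) belongs to the immune cell and the host defence list. Of 8 fibroblast genes 1 was higher, Postn (3.40, SE 0.54), and 2 were lower. In this list 3 passed when adjusted over the list alone (camera, adjusted p = 0.375).

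In all, 2253 genes passed, 1115 higher and 1138 lower in myoepithelial cells, 1710 of them at least 2-fold, and 2253 of the 2253 had the same direction within both replicate numbers. With adjustment over the list alone, 13 contractile, 21 cell cycle, 10 epidermal differentiation, 5 wound keratin, 8 basal keratinocyte, 5 Notch, 5 basement membrane, 9 host defence and 7 immune cell genes passed. The contractile list (camera, adjusted p = 3.39e-15, and adjusted p = 0.108 with an estimated correlation) and the cell cycle list (adjusted p = 1.02e-19, and adjusted p = 0.108 with an estimated correlation) shifted as sets. So did the epidermal differentiation list (adjusted p = 2.73e-05, and adjusted p = 0.204 with an estimated correlation), the wound keratin list (adjusted p = 0.00201, and adjusted p = 0.308 with an estimated correlation) and the immune cell list (adjusted p = 0.000373, and adjusted p = 0.342 with an estimated correlation). The host defence list gave 0.0168 (adjusted p = 0.308 with an estimated correlation). The basement membrane list gave 0.0190 (adjusted p = 0.566 with an estimated correlation) and did not pass fry, which tests against no change (0.114). The Notch and basal keratinocyte lists did not shift as sets (adjusted p = 0.0700 and 0.569). The count of genes was 1404 without myoepithelial array 1, 1173 without myoepithelial array 2 and 1153 without duct basal array 2.

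**Figure D3:**
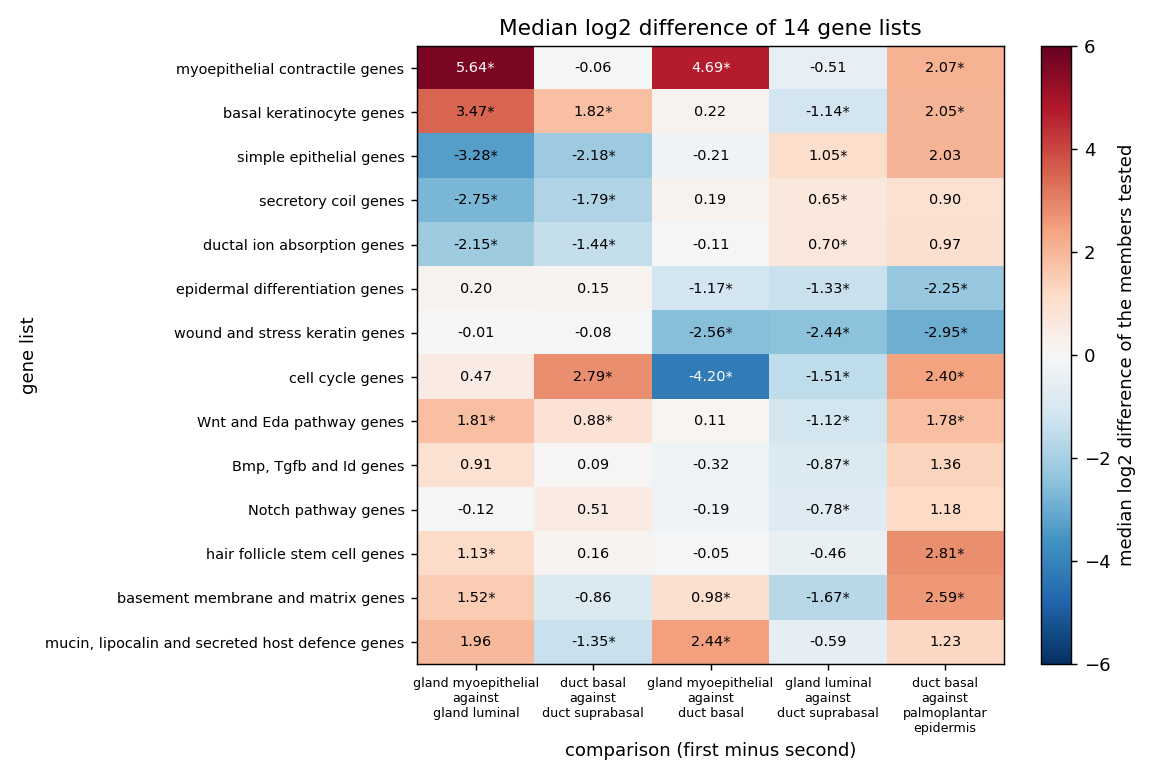
Median log2 difference of the tested members of 14 gene lists (vertical axis) in 5 comparisons (horizontal axis), with colour from -6 to 6 and a star where the list passed camera with its preset correlation. The cell cycle list stood at 2.79 in duct basal against suprabasal cells and at -4.20 in myoepithelial against duct basal cells, and no star held with an estimated correlation.

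Luminal and duct suprabasal cells are the inner layers of coil and duct. Duct suprabasal cells held epidermal differentiation, wound keratin, basal keratinocyte and cell cycle transcripts that were lower in luminal cells, and fewer genes were higher than lower in luminal cells. Epidermal differentiation genes were lower in luminal cells for 9 of 19 members, with Krtdap at -6.17 (SE 0.66, adjusted p = 0.000994) and Krt1 at -5.04 (SE 0.35, adjusted p = 0.000123). Wound keratin genes were lower for 6 of 9, including Krt6a (-4.81) and Krt17 (-3.67), and basal keratinocyte genes for 7 of 15, including Krt14 (-4.16, SE 0.45) and Krt5 (-3.60, SE 0.51). Cell cycle genes were lower for 14 of 21, with Mcm6 at -1.70 (SE 0.27) and Cdc20 at -1.62 (SE 0.40). Birc5 stood at -3.17 (SE 0.34) but did not meet the naming rule. In the Notch pathway Jag1 (-3.97, SE 0.27) and Nrarp (-3.67, SE 0.32) were among 4 lower genes of 14. In the Bmp, Tgfb and Id list 5 of 17 genes were lower, with Id3 at -3.63 (SE 0.99). Bmp2 (-3.54, SE 0.36) was among them but did not meet the naming rule. Gja1, the connexin 43 gene, was lower by -5.71 (SE 0.41). On the luminal side, Fbxo2 (3.05, SE 0.39, adjusted p = 0.00204) and the glycolytic phosphofructokinase gene Pfkl (2.70, SE 0.29, adjusted p = 0.000993) were higher.

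None of the 15 simple epithelial genes passed between these populations, with Krt8 at 1.33 and Krt18 at 1.23. Across all genes tested, duct suprabasal array 1 had correlations of 0.907 and 0.917 with luminal arrays 1 and 2 and of 0.908 with duct suprabasal array 2. Duct suprabasal array 2 had correlations of 0.795 and 0.837 with luminal arrays 1 and 2. Array 1 was thus about as close to the luminal arrays as to the other array of its own population. It is the duct suprabasal array kept wherever array 2 is left out. Fibroblast genes were lower in luminal cells for 6 of 8 members and endothelial genes for 7 of 8, with Pecam1 at -4.75 (SE 0.74) and the vascular genes Aplnr (-6.10) and Plvap (-5.21) among the lowest values of all genes.

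Between luminal and duct suprabasal cells 1405 genes passed, 459 higher and 946 lower in luminal cells (32.7% higher), 1074 at least 2-fold. Within both replicate numbers, 1405 of the 1405 had the same direction. With quantile normalization the split was 589 higher and 783 lower (42.9% higher), and the median log2 difference of all genes moved from -0.06 to 0.08. Adjusted over the list alone, 10 epidermal differentiation, 7 wound keratin, 7 basal keratinocyte, 15 cell cycle, 6 Notch, 7 Bmp, Tgfb and Id, 0 simple epithelial, 8 fibroblast and 8 endothelial genes passed. The epidermal differentiation list (camera, adjusted p = 1.11e-05, and adjusted p = 0.204 with an estimated correlation), the wound keratin list (adjusted p = 4.96e-05, and adjusted p = 0.204 with an estimated correlation), the basal keratinocyte list (adjusted p = 0.000196, and adjusted p = 0.204 with an estimated correlation) and the cell cycle list (adjusted p = 5.42e-09, and adjusted p = 0.183 with an estimated correlation) were shifted down as sets. The same held for the Notch list (adjusted p = 0.00516, and adjusted p = 0.333 with an estimated correlation), the fibroblast list (adjusted p = 5.68e-05, and adjusted p = 0.353 with an estimated correlation) and the endothelial list (adjusted p = 1.69e-05, and adjusted p = 0.342 with an estimated correlation). The Bmp, Tgfb and Id list gave 0.0130 (adjusted p = 0.366 with an estimated correlation) and missed the threshold without duct suprabasal array 2 (0.107) and without that array and myoepithelial array 1 together (0.0932). The simple epithelial list was shifted up (adjusted p = 0.0263, and adjusted p = 0.634 with an estimated correlation). It missed the threshold without duct suprabasal array 2 (0.274), without luminal array 2 (0.0866), without duct suprabasal array 2 and myoepithelial array 1 together (0.0549), with quantile normalization (0.0941) and with fry (0.412). The secretory coil list, with 1 of 16 genes higher and 1 when adjusted over the list alone, was also shifted up (adjusted p = 0.0248, and adjusted p = 0.552 with an estimated correlation). It missed the threshold without duct suprabasal array 2 (0.161), without that array and myoepithelial array 1 together (0.0523), with quantile normalization (0.0510) and with fry (0.378). The ductal ion absorption list, with 0 of 10 past the threshold over all genes or the list alone, gave 0.0401 (adjusted p = 0.566 with an estimated correlation). That call ended without duct basal array 2 (0.0503), duct suprabasal array 2 (0.255) or luminal array 2 (0.124), without duct suprabasal array 2 and myoepithelial array 1 together (0.130), and with fry (0.378). Of 15 basement membrane genes 7 were lower, and 9 when adjusted over the list alone. Their list gave 0.00516 (adjusted p = 0.523 with an estimated correlation) and missed the threshold with fry (0.0678) and without duct suprabasal array 2 and myoepithelial array 1 together (0.0789). The count of genes was 273 without luminal array 1, 502 without luminal array 2, 908 without duct suprabasal array 2 and 28 in a fit of only the 4 arrays compared.

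Duct basal cells were set against the palmoplantar epidermis into which the duct opens. Duct basal cells held more transcript of cell cycle, hair follicle stem cell, basement membrane and early response genes, and epidermis more of epidermal differentiation. The sample titles name a layer for duct basal cells and none for the epidermis. Differences of layer and of tissue therefore cannot be told apart here. Of 21 cell cycle genes 20 were higher in duct basal cells, with Top2a at 3.21 (SE 0.31, adjusted p = 0.000132) and Mcm4, a subunit of the replicative helicase, at 3.07 (SE 0.38). Of 11 hair follicle stem cell genes 8 were higher and none lower, including the transcription factor genes Runx1 (5.50, SE 0.59, adjusted p = 0.000198), Foxc1 (5.49, SE 0.46) and Sox9 (5.24, SE 0.52). Basement membrane genes were higher for 12 of 15 members, led by Thbs1 (6.28), and basal keratinocyte genes for 10 of 15, with Lamb3 (4.23) and Itgb4 (3.81) higher and Sfn (-2.69) lower. Of 12 early response genes 11 were higher in duct basal cells, among them Nr4a1 (5.84, SE 0.48) and Fos (4.61, SE 0.27, adjusted p = 2.51e-05). Fos had a signal of 24183 ± 5621 (SD, n = 2) in duct basal cells and 982 ± 278 in epidermis. The higher level of early response genes was not particular to duct basal cells. Their median log2 level exceeded that of epidermis by 2.87 in duct basal, 1.89 in duct suprabasal, 2.68 in myoepithelial and 3.32 in luminal cells.

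Epidermal differentiation genes were lower in duct basal cells for 11 of 19 members and higher for none, with Tgm1, the gene of an enzyme that crosslinks the cornified envelope, at -3.80 (SE 0.38, adjusted p = 0.000145) and Dsc1, a desmosomal cadherin gene, at -3.68 (SE 0.48, adjusted p = 0.000573). Wound and stress keratin genes were split, with 5 of 9 lower, including Krt6b (-5.43) and S100a8 (-3.74), and 3 higher. Simple epithelial genes were higher for 8 and lower for 2 of 15, with Krt8 at 5.92 (SE 0.47) and Krt18 at 5.73. Of 13 contractile genes 8 were higher, with the myosin light chain kinase gene Mylk at 4.18, for which 1 of 3 probe sets had the opposite sign and did not pass. The largest difference of all was Atp1b1, the beta subunit gene of the sodium pump (8.91, SE 0.76, adjusted p = 7.41e-05). Id4 (6.52) and Wfdc2 (6.60) were also among the highest, and Gsta2, a glutathione transferase gene, was the lowest (-6.94, SE 0.71). Fibroblast genes were higher in duct basal cells for 6 of 8 members, with Col3a1 at 4.46 (SE 0.63), a signal of 733 ± 29.1 against 22.1 ± 4.17. Whether the fibroblast and basement membrane transcripts came from other cells in the duct basal samples was not tested.

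Here 3141 genes passed, 2131 higher and 1010 lower in duct basal cells (67.8% higher), 2369 at least 2-fold. The direction was the same within both replicate numbers for 3141 of the 3141. With quantile normalization 1489 were higher and 1128 lower (56.9% higher), and the median log2 difference of all genes moved from 0.24 to 0.01. Adjusted over the list alone, 20 cell cycle, 9 hair follicle stem cell, 12 basement membrane, 12 basal keratinocyte, 12 early response, 12 epidermal differentiation, 8 wound keratin, 10 simple epithelial, 8 contractile and 7 fibroblast genes passed. As sets, the cell cycle list (camera, adjusted p = 5.63e-09, and adjusted p = 0.183 with an estimated correlation), the hair follicle stem cell list (adjusted p = 0.000142, and adjusted p = 0.183 with an estimated correlation), the basement membrane list (adjusted p = 0.000193, and adjusted p = 0.380 with an estimated correlation) and the basal keratinocyte list (adjusted p = 0.000406, and adjusted p = 0.210 with an estimated correlation) were shifted up. The early response list (adjusted p = 1.49e-05, and adjusted p = 0.333 with an estimated correlation), the contractile list (adjusted p = 0.00201, and adjusted p = 0.333 with an estimated correlation) and the fibroblast list (adjusted p = 0.00272, and adjusted p = 0.492 with an estimated correlation) were also shifted up. The epidermal differentiation list (adjusted p = 5.96e-08, and adjusted p = 0.161 with an estimated correlation) and the wound keratin list (adjusted p = 0.00739, and adjusted p = 0.333 with an estimated correlation) were shifted down. The simple epithelial list was not called (adjusted p = 0.130). The count of genes was 1739 without duct basal array 1, 1715 without epidermis array 1 and 1859 without epidermis array 2.

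The difference between outer and inner layer was itself compared between gland and duct, as myoepithelial minus luminal minus the difference of duct basal minus suprabasal. The contractile genes had the larger difference in the gland, and the cell cycle genes in the duct. The collagen IV genes were higher in the outer layer of the gland and in the inner layer of the duct. Whether their transcript in duct suprabasal cells came from fibroblasts or vessels was not tested. All 13 contractile genes differed, with Myh11 at 8.16 (SE 0.65, adjusted p = 0.000297) and Cnn1 at 7.29 (SE 0.50), and Col4a1 stood at 8.38 (SE 0.92), from 5.39 in the gland and -2.99 in the duct. Of 21 cell cycle genes 16 differed in the opposite sense, with Cdk1 at -4.20 (SE 0.35, adjusted p = 0.000325) and Cdc20 at -3.15. Of 12 mucin, lipocalin and host defence genes 6 were higher, with Clu at 6.05 (SE 0.76), 2.70 in the gland and -3.35 in the duct. Of 15 basal keratinocyte genes 9 were higher, among them Lama3 (5.82) and Trp63 (3.47, SE 0.30), and Itgb4 was lower (-2.69, SE 0.33). The greatest differences, of Fmod (10.35, SE 1.52) and Scara5 (10.29, SE 1.11), were of genes with a wide spread between the duct suprabasal arrays, whose signals were 4949.8 ± 5962 for Fmod and 2182 ± 2225 for Scara5 (SD, n = 2).

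Markers of other cells moved in the same comparison. Immune cell genes were higher for 4 of 7 members, with Tyrobp at 4.90 (SE 0.92) and Fcer1g, a subunit of myeloid Fc receptors, at 4.91 (SE 0.83), and Lyz2 is shared with the host defence list. Fibroblast genes were higher for 1 of 8 members, Postn (5.05, SE 0.77), and endothelial genes for 2 of 8, and none was lower in these lists. With adjustment over each list alone, 7 immune cell, 4 fibroblast and 5 endothelial genes passed. The immune cell list shifted as a set (camera, adjusted p = 0.000342, and adjusted p = 0.342 with an estimated correlation). The endothelial list gave 0.00492 (adjusted p = 0.523 with an estimated correlation) and missed the threshold with fry in place of camera (0.0983) and without myoepithelial array 1 and duct suprabasal array 2 together (0.0719). The fibroblast list gave 0.0198 (adjusted p = 0.566 with an estimated correlation) and missed it without duct suprabasal array 2 (0.161), without luminal array 1 (0.0590), without myoepithelial array 1 and duct suprabasal array 2 together (0.146), and with fry (0.175).

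The test of the layer differences called 1467 genes, 921 with a higher and 546 with a lower value (62.8% higher), 1416 of them at least 2-fold. For 1467 of the 1467 the direction was the same within both replicate numbers. With quantile normalization the split was 771 and 755 (50.5% higher), and the median over all genes moved from 0.05 to -0.14. With adjustment over the list alone, 13 contractile, 19 cell cycle, 8 host defence and 11 basal keratinocyte genes passed. The contractile list (camera, adjusted p = 5.51e-15, and adjusted p = 0.108 with an estimated correlation), the cell cycle list (adjusted p = 1e-12, and adjusted p = 0.140 with an estimated correlation), the host defence list (adjusted p = 0.00201, and adjusted p = 0.204 with an estimated correlation) and the basal keratinocyte list (adjusted p = 0.000551, and adjusted p = 0.215 with an estimated correlation) shifted as sets. The count of genes was 749 without luminal array 1, 689 without luminal array 2, 651 without myoepithelial array 2 and 615 without duct basal array 2.

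Genes that set 1 population apart from each of the 4 others by at least 2-fold numbered 1081. They were 176 in duct basal, 117 in duct suprabasal, 321 in myoepithelial, 123 in luminal and 344 in epidermal cells. The duct basal set was led by Rbp4, which encodes the retinol carrier of plasma (smallest of the 4 log2 differences 3.51), and included the mitotic genes Aspm (3.28) and Top2a (3.21). Rbp4 had a signal of 6349 ± 1392 (SD, n = 2) in duct basal and 686 ± 608 in duct suprabasal cells. The myoepithelial set was led by Myh11, Cnn1, Pcp4, Myl9 and Sln, the luminal set by Mucl2, Fbxo2, Itih4, Pfkl and Cited4, and the epidermal set by Sprr1b, Teddm3, Elovl4, Gsta2 and Serpina12. The 5 leading genes of the duct suprabasal set were Esm1, Dpt, Aplnr, Gdf10 and Flt1. Of the 117 duct suprabasal genes 97 (82.9%) were at least 2-fold brighter on array 2 than on array 1, against 1024 (11.0%) of all genes tested. Without myoepithelial array 1 and duct suprabasal array 2, a choice made after the data were seen, the duct suprabasal set held 69 genes and the luminal set 75. The duct basal set held 111 genes without duct basal array 1 and 104 without duct basal array 2, and the myoepithelial set 210 and 151 without myoepithelial arrays 1 and 2. The luminal set held 15 genes without luminal array 1, 19 without luminal array 2, 270 without duct suprabasal array 1 and 45 without duct suprabasal array 2. The duct suprabasal set ranged from 23 genes without luminal array 1 to 240 without duct suprabasal array 1, and the omission of any array moved it by more than 1.5 times.

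Counts for the other pairs of populations came from the same fit. Epidermis differed from myoepithelial cells at 4774 genes, from luminal cells at 4194 and from duct suprabasal cells at 4248, while luminal cells differed from duct basal cells at 3271 and duct suprabasal from myoepithelial cells at 1602.

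**Figure D4:**
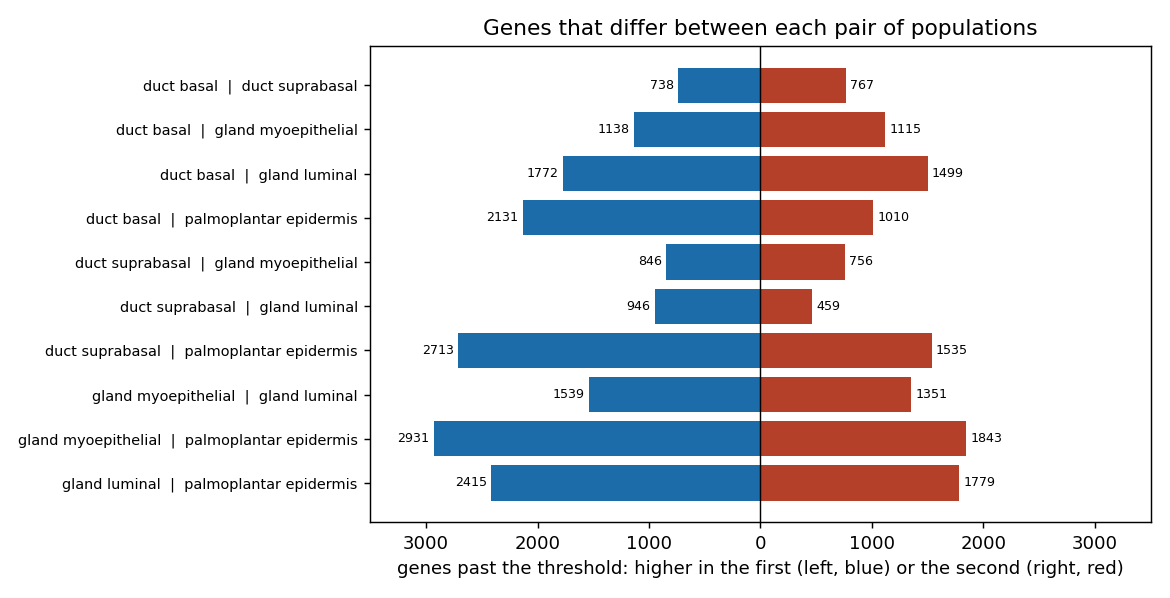
Genes past an adjusted p of 0.05 for each pair of populations (horizontal axis, number of genes), with genes higher in the population named on the left as blue bars and in the other as red bars. Counts were 459 and 946 for luminal against duct suprabasal cells and 2931 and 1843 for myoepithelial cells against epidermis.

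The remaining marker lists were tested in all 6 comparisons. The pericyte and melanocyte lists passed in 0 of the 6 comparisons (camera, smallest adjusted p = 0.154 and 0.170), though 3 of 4 pericyte genes were higher in duct basal cells than in epidermis. The Schwann cell list passed in 2, between duct basal cells and epidermis with 3 of 3 genes higher (adjusted p = 0.0108, and adjusted p = 0.210 with an estimated correlation) and between the duct layers with 1 of 3 lower (adjusted p = 0.0263, and adjusted p = 0.257 with an estimated correlation), a call that ended without duct basal array 2 (0.0526). Its members Sox10, Mbp and Pmp22 are also expressed in epithelia of glands or skin. The Merkel cell list had 0 tested members, the red blood cell list 1 (Alas2), the skeletal muscle list 2 (Acta1 and Mylpf) and the adipocyte list 2 (Adipoq and Fabp4), too few for a test. Fabp4, which capillary endothelium also expresses, had a signal of 12958 ± 13493 (SD, n = 2) in duct suprabasal and 1007 ± 781 in duct basal cells. Adipoq was lower in duct basal than in duct suprabasal cells (-3.21, SE 0.71, limma, adjusted p = 0.0182). It was also lower in luminal than in duct suprabasal cells (-3.77, SE 0.71, limma, adjusted p = 0.00986). Both adipocyte genes were brighter on duct suprabasal array 2 than on array 1, by a median log2 ratio of 2.43.

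The early response list, which passed between duct basal cells and epidermis, also passed in 3 other comparisons in which few of its 12 members did. Between luminal and duct suprabasal cells 1 was higher, and 1 when adjusted over the list alone (camera, adjusted p = 0.00201, and adjusted p = 0.468 with an estimated correlation), a call that ended with fry in place of camera (0.159). Between the duct layers 1 was higher in basal cells, and 0 when adjusted over the list alone (adjusted p = 0.0183, and adjusted p = 0.548 with an estimated correlation). That call ended without duct basal array 2 (0.570), without duct suprabasal array 2 (0.119), without that array and myoepithelial array 1 together (0.0883), with quantile normalization (0.204) and with fry (0.226). In the test of the layer differences 1 was lower, and 1 when adjusted over the list alone (adjusted p = 0.0108, and adjusted p = 0.524 with an estimated correlation). This call ended without duct basal array 2 (0.123), with quantile normalization (0.0941) and with fry (0.205).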

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

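The tests of explanations in this part were chosen after the results were seen. A difference between gland and duct marked the layer comparison: the layer difference in the gland and that in the duct differed, by a test of the difference itself, at 1467 genes. The named genes with the highest values were Fmod (10.35), Scara5 (10.29), Col4a1 (8.38), Myh11 (8.16), Col4a2 (8.13), Tgm2 (8.10), Tagln (7.63) and Pcp4 (7.61). Part of the values of Col4a1 and Col4a2 came from the duct (-2.99 and -2.81), where suprabasal cells were higher. Fmod and Scara5 had a wide spread between the duct suprabasal arrays. Whether other cells in the duct suprabasal samples raised these 4 values was not tested. Those with the lowest were Mucl2 (-5.95), Racgap1 (-4.95), Fads3 (-4.74), Prxl2a (-4.24), Cdk1 (-4.20), Fads2 (-4.18), Cks2 (-4.03) and Melk (-4.03).

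Fibroblast and endothelial transcripts in duct suprabasal cells could come from such cells in the sorted sample, in a larger share on array 2. The smaller of the list medians of the log2 ratio of array 2 over array 1 was 2.35, but this is the observation that raised the explanation and does not test it, so it stays open. A scaling difference of the whole array is excluded, since 0% of 10000 random lists matched on expression had a median ratio as large. The labels do not give the markers used for sorting, and no biological explanation was tested.

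Luminal transcripts on myoepithelial array 1 could come from luminal cells in that sample. Over 164 luminal genes the excess on array 1 was a median of 16.5% of the luminal level (quartiles 13.6% and 19.8%). These genes were picked as dim on array 2, which favours an excess on array 1. The excess therefore restates the observation and does not test the explanation, which stays open. The share varied little between genes, as a mixture with luminal cells would give. For 84 duct basal and epidermal genes, also dim on array 2, the share had a median of -0.57% and an upper quartile of 0.172%. This argues against a scaling difference. However, these genes were picked as no brighter in luminal cells than on array 2, which favours low shares. A change of state within myoepithelial cells was not tested.

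Early response genes were lower in epidermis than in duct basal cells, and scaling of the darker epidermis arrays could produce this. It is excluded, since the median log2 difference was 3.74 before and 3.51 after quantile normalization. A different isolation or handling of the epidermis may also lower these genes. The medians of the 4 other populations ranged over 1.42. Whether the epidermis was dissociated and handled like the others is not known here, so handling and biology cannot be separated.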

How the results depend on the processing

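Of 415 named gene results, 247 kept their direction and their side of the threshold under every alternative that could be run on them, 167 lost the threshold under some, and 1 reversed. The fit of only the arrays compared covered 354 of them, since it has no counterpart for the 61 results on layer differences, the choice of probe sets 401 and the higher filter 412. Those called under every alternative run were 58 of 74 for myoepithelial against luminal cells, 19 of 67 for the duct layers, 53 of 74 for the outer layers, 6 of 53 for the inner layers, 74 of 86 for duct basal cells against epidermis and 37 of 61 for the layer differences, which faced fewer alternatives. The reversal was Acta2 in duct basal cells against epidermis, at -0.27 without probe sets that may match several transcripts, where another probe set stands for the gene. List calls were repeated only with fry, quantile normalization, the replicate block and arrays left out, under which 45 of 64 held, and with the estimated correlation, under which 0 held, or 0 with the replicate block as well. With all probe sets 4370 passed between myoepithelial and luminal cells and 9391 in the F test, as more features were tested. In fits of only the 4 arrays compared, 223 genes passed between the duct layers and 28 between the inner layers. Such fits have fewer arrays to estimate the spread, and both of these hold the duct suprabasal arrays. The SD of the log2 difference between arrays was 0.881 in duct suprabasal cells and 0.474 to 0.591 in the other populations. The fit of all 10 arrays gives every population the same spread, so its p-values for duct suprabasal cells may be too small. Leaving out each array in turn gave 1422 to 3451 genes for myoepithelial against luminal cells, 430 to 1960 for the duct layers, 1153 to 2819 for the outer layers, 273 to 2033 for the inner layers, 1715 to 3719 for duct basal cells against epidermis and 615 to 2014 for the layer differences; the cause was not tested. The replicate block gave 3281, 2013, 2678, 1863, 3560 and 1937 genes in the same order, all within 1.5 times, and ended 1 list call, of hair follicle stem cell genes between myoepithelial and luminal cells (0.0649). The deviations of arrays with the same number were positively correlated in 10 of 10 pairs of populations, above 0.1 in 6. Leaving out myoepithelial array 1 and duct suprabasal array 2 together, chosen after seeing the data, gave 2820, 2094, 2143, 946, 3759 and 1444. On arrays, signals near background limit what can be called for genes of low expression.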

Other observations

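The gene families here were chosen after the data were seen. Subunit genes of the vacuolar ATPase, the proton pump that acidifies lysosomes and endosomes, were lower in myoepithelial than in luminal cells for 14 of 18 members and higher for 0 (median log2 difference -1.42, camera of limma, adjusted p = 5.93e-07, and adjusted p = 0.811 with an estimated correlation). Proteasome genes were lower in duct basal cells than in epidermis for 21 of 38 members and higher for 0 (median -0.68, or -0.57 with quantile normalization, adjusted p = 3.56e-10, and adjusted p = 0.811 with an estimated correlation). Over 25 families and 150 tests 29 passed with the preset correlation and 0 with the estimated correlation.

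The ratio of labelling control transcripts to hybridization control transcripts was between 0.259 and 0.543 on the arrays numbered 1 and between 1.41 and 1.92 on those numbered 2. These ranges did not overlap, and the main model does not account for the replicate number. The ratio of 3′ to 5′ actin signal ranged from 2.44 to 7.79 over the 10 arrays. Duct basal arrays had 7.79 and 4.88 against 3.30 and 2.51 in epidermis. Myoepithelial arrays had 3.49 and 6.52 against 2.44 and 3.60 in luminal cells. The same ratio of Gapdh was 1.86 and 1.83 in duct basal cells against 0.964 and 0.853 in epidermis. For Gapdh it was 1.30 and 2.68 in myoepithelial against 0.895 and 0.872 in luminal cells. These ratios thus differed between some of the populations compared, and their effect was not tested.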
